A study of Mus musculus with 10 samples.

How the data were processed

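Platelets of adult mice were sorted from peripheral blood into Tomato+ and Tomato- fractions, complementary DNA was made with a Smart-seq+ protocol from polyadenylated RNA, and libraries were built with the Nextera XT kit, per the labels' protocols. Such full-length amplification carries no molecular identifiers in the counts used here, so reads are not independent molecules, and intervals or limits that come from counts cover counting error only. The 10 libraries fall into 5 Tomato+ and 5 Tomato- libraries, numbered 1 to 5 in each group by their titles. The labels do not say whether libraries of a group came from separate animals, so all p-values measure the spread between these libraries, which may be technical.

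The authors deposited raw read counts per gene for the 10 libraries in 1 table, with gene symbols as row names and no normalization. Trimmomatic, FastQC, STAR and featureCounts are named in the submitters' processing notes, without versions, together with the mouse genome build mm10. The annotation, the strand setting and the handling of reads with several alignments are not given in the sources used here. Counts of genes with near-identical copies, such as haemoglobin, ribosomal protein and MHC class I genes, are therefore uncertain, and reads of overlapping or antisense genes cannot be told apart. Of the 23420 symbols, 21777 (93%) matched a gene name in GENCODE M21, which annotates GRCm38, the assembly that mm10 names; coordinates come from that annotation. The table's row Beta-s was matched to the haemoglobin gene Hbb-bs through an older symbol. No row matched the 13 mitochondrially encoded protein genes, which were not analysed here, so the planned share of mitochondrial counts was not computed.

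Library sizes for CPM were the sums of all rows. In edgeR, the list tests and voom they were the sums over the genes kept for the test, 93.85 to 95.39% of counts in the main test. Scaling by total counts means these sums without a further factor. Levels are given as counts per 1000000 counts of the library (CPM), mean ± SD over 5 libraries. No pair among 45 pairs of libraries agreed within sampling noise (lowest chi-square per degree of freedom 887), so all were kept as separate replicates. A gene was called detected in a library at 1 count or more. Where a library had 0 counts, the limit that 3 counts would give ranged from 0.185 to 0.554 CPM.

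Genes were compared with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust fit, TMM factors, the default expression filter with its minimum count of 10 and minimum total of 15) and Benjamini-Hochberg adjustment at 0.05. A prior count of 2 was set for log2 CPM in the correlations of same-numbered libraries, not for the gene test. The group was the sole term. Log2 fold changes are Tomato+ over Tomato-, with SE taken from the fold change and its F statistic. They are on the TMM scale, which lies 0.24 above the total-count scale for this contrast, so CPM and log2 fold changes can differ in sign for small differences. Of 26 gene lists fixed before the data were examined, the 10 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and with fry. Totals on the log10 scale, detected genes and the shares of counts were compared by exact two-sided permutation of the group labels over 252 assignments, where the p doubles the smaller tail and the smallest possible p is 0.00794, with Benjamini-Hochberg adjustment over the 5 measures.

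The genes named in the text follow a rule set before the data were examined. In each direction it takes up to 12 genes past the threshold or, where fewer than 5 passed, the 5 with the smallest p, leaving out predicted gene models. It always takes Vwf, Flt3, Itga2b, Itgb3, Gp1ba, Gp9, Pf4, Ppbp, Selp, Gata1 and Tubb1, and 1 further gene that is not reported here. It adds up to 4 members with the smallest p from each list described and the 2 most abundant members of each list of another cell type. Any gene named outside the rule is marked as chosen after its values were seen.

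The edgeR and list tests were tested on simulated counts, in 5 simulations with 200 changed genes each. They were drawn from the means and library sizes of these genes and from their dispersions, estimated without the group. Among genes with a count in every library, 0% of those changed 2-fold, 17.6% of those changed 4-fold and 63.1% of those changed 16-fold were called. For genes missing from some libraries these shares were 0%, 1.53% and 4.07%. With the test run on the 225 genes that had 10 counts in every library and 60 changed genes per simulation, they were 21%, 78% and 97%, with 9 of 825 unchanged genes called. A list raised 2-fold was called in 3 of 5 simulations, and 0 of 45 tests of other lists were called. Simulated genes were drawn independently of each other, whereas the estimated correlation within the real lists ranged from 0.13 to 0.41. The simulated calls of lists therefore do not describe the list test on the real counts. Losses shared by many genes of a library were not simulated either, so the shares of genes called above may not hold for the real counts.

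Alternatives set before the data were examined were the replicate number as a block, DESeq2 size factors or upper-quartile factors in edgeR, no filter, a filter of 10 counts in 5 libraries, haemoglobin genes left out, thinning of each library to the smallest total (5411417 counts), leaving out each library, DESeq2 1.42.0, limma voom with quality weights (with and without the block), a threshold of 0.10, an estimated correlation, fry, and detection at 10 counts. Alternatives chosen after seeing the data were scaling by total counts, the 225 genes with 10 counts in every library (in edgeR, in edgeR with the block and in DESeq2), leaving out the 3 libraries with under 1000 detected genes with or without Tomato+ replicate 3, an exact p from the absolute difference with each library left out, and, for the share of the 10 highest genes, thinning, the block, leaving out Rn45s and leaving out the same 3 libraries. Permutation tests and figures used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.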

Results

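The RNA of platelets, the anucleate fragments that megakaryocytes shed into the blood, was sequenced from 5 Tomato+ and 5 Tomato- libraries sorted from mouse peripheral blood. Tomato is a red fluorescent protein, and which gene drives it is not given in the sources used here. The comparison asks which transcripts differ between platelets with and without the reporter. Total counts per library ranged from 5.41 to 16.2 M (M, 1000000 counts), with 11.9 ± 3.57 M in Tomato+ and 8.55 ± 2.16 M in Tomato- (mean ± SD, n = 5 each). Of 23420 listed genes, 4692 had a count in any library and 264 had one in every library. Those 264 genes carried 78.8% of all counts, while 2008 genes had counts in 1 library alone. The sample numbers in the titles run from 1 to 5 for Tomato+ and from 6 to 10 for Tomato-, so any effect of that order and the group cannot be told apart.

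Both fractions were dominated by the same abundant platelet transcripts. Tmsb4x, which encodes the actin-sequestering peptide thymosin beta 4, took 12.8 ± 1.46% of counts in Tomato+ and 11.4 ± 1.35% in Tomato- libraries. Ctla2a followed with 4.93 ± 0.612% and 4.95 ± 0.421%, and the ribosomal RNA precursor Rn45s with 5.52 ± 1.64% and 3.80 ± 1.38%. Actb (cytoplasmic beta actin) took 2.88 ± 0.268% and 2.88 ± 0.469%, Fth1 (ferritin heavy chain) 2.84 ± 0.366% and 2.88 ± 0.513%, and the tetraspanin Cd9 2.63 ± 0.401% and 2.41 ± 0.315%. Ctla2a and Fth1 are named here for their rank among the most abundant genes, after their values were seen.

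No gene passed the test between Tomato+ and Tomato- platelets. Among 1016 genes tested with edgeR, 0 were higher and 0 were lower at an adjusted p under 0.05, and the smallest adjusted p was 0.9996. At an unadjusted p under 0.05 there were 9 genes, 8 higher and 1 lower in Tomato+, where 50.8 would be drawn by chance from uniform p-values. On the 225 genes with 10 counts in every library, a set chosen after seeing the data, 7 were higher and 6 lower at an unadjusted p under 0.05. With limma voom without the replicate block the count was also 0. With the block, limma voom called Rn45s (log2 fold change 0.18, SE 0.0035, adjusted p = 0.000576) and Nrgn (0.43, adjusted p = 0.00268). The SE of Rn45s did not cover the spread between its same-numbered libraries, so that call is not read as a difference. DESeq2 called 217 genes, 181 of which had no count at all in 1 of the groups. The median over all DESeq2 calls was 2 libraries with counts. The median log2 fold change of the tested genes was 0.21 on the TMM scale and -0.03 with scaling by total counts.

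**Figure D1:**
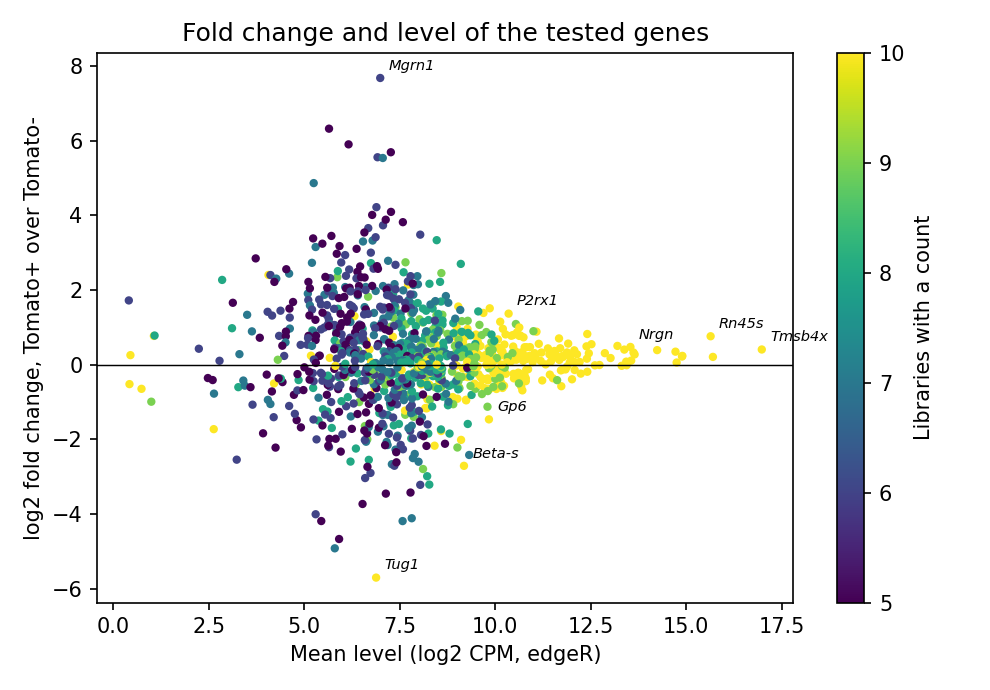
Log2 fold change of Tomato+ over Tomato- (vertical axis) against mean level in log2 CPM (horizontal axis) for the 1016 tested genes, coloured by the number of libraries with a count. The median absolute log2 fold change was 0.33 for the 255 genes with a count in every library, with Tug1 (-5.70) as an exception among them, and 0.87 for the other 761 genes, among them Mgrn1 (7.67).

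The 5 genes with the smallest p on the Tomato+ side were Tmsb4x, Nrgn, Rn45s, Dap and Mgrn1, none of which passed in edgeR (adjusted p = 0.9996 for each). Nrgn and Rn45s passed in limma voom with the replicate block, and Mgrn1 passed in DESeq2 (adjusted p = 0.0134). Tmsb4x and Dap passed in neither. Tmsb4x (chromosome X, 167207093 to 167209315, minus strand, GRCm38) had 128000 ± 14600 CPM in Tomato+ and 114000 ± 13500 CPM in Tomato- (log2 fold change 0.41, SE 0.10, n = 5 each). With scaling by total counts its log2 fold change was 0.17. Nrgn, which encodes the calmodulin-binding protein neurogranin (chromosome 9, 37544492 to 37552904), had 12200 ± 1750 and 10400 ± 2410 CPM. Dap (chromosome 15, 31224314 to 31274341) had 6060 ± 1730 and 3840 ± 1380 CPM. Without the 3 libraries with under 1000 detected genes, all Tomato-, the log2 fold change of Dap was 0.28 in place of 0.82, and that of Rn45s 0.40 in place of 0.76. Mgrn1, a ubiquitin ligase gene on chromosome 16 (4886249 to 4938296), had counts in 4 Tomato+ libraries, between 89.1 and 692 CPM, and in 2 Tomato- libraries, at 0.757 and 4.44 CPM.

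On the Tomato- side the 5 genes with the smallest p were Tug1, Gp6, Beta-s, Clcn3 and Spa17, again with an adjusted p of 0.9996 each in edgeR. Tug1 passed in DESeq2 (adjusted p = 0.00852). On the genes with 10 counts in every library, a set chosen after seeing the data, DESeq2 called Tug1 (adjusted p = 0.000990) and Clcn3 (adjusted p = 0.0405) but not Gp6 (adjusted p = 0.110). Gp6, the collagen receptor glycoprotein VI (chromosome 7, 4363965 to 4397744), had 429 ± 227 CPM in Tomato+ and 1480 ± 910 CPM in Tomato- (log2 fold change -1.46, SE 0.72, 95% interval -3.00 to 0.07). Its 3 highest Tomato- libraries, replicates 1, 2 and 5, were the 3 libraries with under 1000 detected genes, and without these the log2 fold change was -0.37. Clcn3, a chloride-proton exchanger gene (chromosome 8, 60910389 to 60983300), had 195 ± 136 and 973 ± 578 CPM, and its log2 fold change of -2.01 was -0.92 without the same libraries. The long noncoding RNA Tug1 (chromosome 11, 3639785 to 3649673) lay between 2.18 and 5.69 CPM in Tomato+ libraries. In Tomato- it had 4.07 to 8.58 CPM in 3 libraries but 154 and 1100 CPM in replicates 4 and 5, and its log2 fold change was -5.70 with all libraries and -3.34 without replicate 5. The haemoglobin row Beta-s had 130 ± 132 and 879 ± 1350 CPM, and its log2 fold change of -2.71 was -0.94 without Tomato- replicate 4. Spa17 had 2.89 ± 4.48 and 118 ± 153 CPM, with 306 and 262 CPM in Tomato- replicates 1 and 5, and its log2 fold change of -4.92 was -1.90 without the 3 libraries with under 1000 detected genes.

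Among the genes set in advance, Vwf, which encodes von Willebrand factor (chromosome 6, 125546774 to 125686679), had 4960 ± 463 CPM in Tomato+ and 5240 ± 1060 CPM in Tomato-. Its log2 fold change was 0.16 (SE 0.22) with a 95% interval of -0.31 to 0.63, so a difference of 2-fold in either direction lay outside the interval, and the sign turned with scaling by total counts (-0.08). Flt3, the receptor tyrosine kinase gene of early progenitors (chromosome 5, 147330741 to 147400489), had 0 counts in all 10 libraries. Counting error alone would allow up to 0.185 to 0.554 CPM by library. Losses between libraries were far larger than that, as Gp1ba ran from 0.185 to 1650 CPM within Tomato-, so these limits do not bound the level of Flt3 in the platelets. Both subunits of the fibrinogen receptor were abundant in both fractions. Itga2b had 8710 ± 2190 and 10200 ± 2330 CPM, and Itgb3 had 1230 ± 384 and 1330 ± 361 CPM. The chemokine Pf4 had 10900 ± 1110 and 11700 ± 2590 CPM, its neighbour Ppbp 19100 ± 2630 and 17300 ± 4050 CPM, and Gp9, a subunit of the von Willebrand factor receptor, 3220 ± 594 and 3200 ± 953 CPM. The platelet tubulin Tubb1 had 3710 ± 1720 and 3540 ± 1590 CPM. For all of these but Flt3, which was not tested, the edgeR adjusted p was 0.9996, with n = 5 per group.

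Other genes set in advance were irregular from library to library. Gp1ba, the ligand-binding subunit of the von Willebrand factor receptor, ranged from 1.17 to 590 CPM in Tomato+ and from 0.185 to 1650 CPM in Tomato-. Its log2 fold change was -0.43 (SE 2.06), and it was 0.62 without Tomato- replicate 2. Selp, which encodes P-selectin, had counts in 1 Tomato+ library (364 CPM) and 1 Tomato- library (24.5 CPM). The transcription factor gene Gata1 had counts in 2 Tomato+ libraries and 1 Tomato- library, with 9.36 ± 20.9 and 12.5 ± 27.9 CPM.

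**Figure D2:**
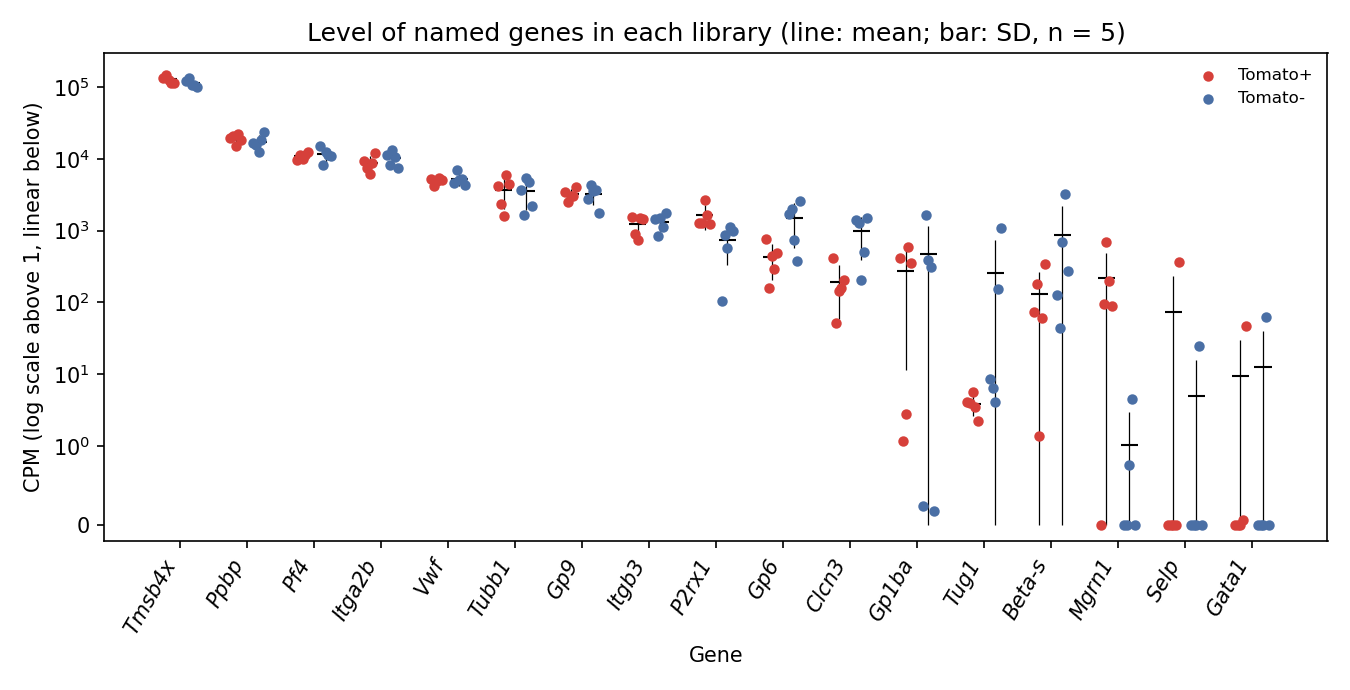
CPM of named genes in each of the 10 libraries (points), with the mean (line) and SD (bar, n = 5) per group, on an axis that is logarithmic above 1 and linear below. From Tmsb4x to Itgb3 the libraries of both groups overlap at similar levels, while Gp1ba, Tug1, Mgrn1, Selp and Gata1 vary within a group from under 10 CPM to far higher levels.

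Surface receptors of platelets had 67500 ± 4370 CPM in sum in Tomato+ and 68000 ± 6130 CPM in Tomato-. Of 21 tested members, 14 had a higher and 7 a lower estimate in Tomato+, and none passed (camera adjusted p = 0.759). With scaling by total counts 10 of the 21 had a higher estimate. P2rx1, the ATP-gated cation channel (chromosome 11, 72999103 to 73015200), had 1630 ± 626 and 735 ± 408 CPM (log2 fold change 1.37, SE 0.63). Cd9 had a log2 fold change of 0.35 (SE 0.17), and Fcer1g, the signalling chain of the glycoprotein VI complex, had 1680 ± 490 and 1040 ± 527 CPM.

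Granule contents had 57800 ± 2550 and 54200 ± 5930 CPM in sum. All 15 tested members had a positive log2 fold change (median 0.39), the list did not pass (camera adjusted p = 0.580), and adjusted p was 0.927 with an estimated correlation. With scaling by total counts 11 of 15 were positive (median 0.15), and without the 3 libraries with under 1000 detected genes 8 of 16 were (median 0.01). Ppbp had a log2 fold change of 0.39 (SE 0.17) and Clu, which encodes clusterin, 0.40 (SE 0.24). Angpt1, which encodes angiopoietin 1, had counts in 5 Tomato+ and 3 Tomato- libraries, with 332 ± 257 and 104 ± 159 CPM (39.1 CPM in Tomato- without replicate 3).

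Signalling proteins and eicosanoid enzymes had 35000 ± 2230 and 40100 ± 3270 CPM in sum. Of 18 tested members, 7 had a higher and 11 a lower estimate, and none passed. Their median log2 fold change was -0.12 but their mean was 0.41, with fitted values of 5.69 and 2.97 for Stim1 and Prkca, which had counts in 5 libraries each. Ptgs1, the cyclooxygenase of platelets, had 1140 ± 339 and 2040 ± 563 CPM (log2 fold change -0.59, SE 0.41), and Gng11, a G protein gamma subunit, had 12200 ± 620 and 11700 ± 1260 CPM. Cytoskeletal proteins took the largest sum of any list, 201000 ± 10700 and 191000 ± 14100 CPM, with 16 of 29 tested members higher, and 10 of 29 with scaling by total counts (median log2 fold change -0.17 in place of 0.08). Tmsb4x was the 1 member of any list that passed when adjusted over the list alone, in the main edgeR fit (log2 fold change 0.41, unadjusted p = 0.0011). On the 225 genes with 10 counts in every library, a set chosen after seeing the data, edgeR gave it 0.25 (unadjusted p = 0.0286). The estimate was smaller still with scaling by total counts. Zyx (zyxin) had 6100 ± 1520 and 4720 ± 1010 CPM, and Wipf1 had counts in 5 libraries.

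Transcription factors of megakaryocytes had 1500 ± 465 and 1290 ± 198 CPM in sum, and 6 of 7 tested members had a higher estimate (median log2 fold change 0.83). Without the 3 libraries with under 1000 detected genes 3 of 12 did (median -0.40). Nfe2, which controls late megakaryocyte genes, had 1030 ± 477 and 800 ± 586 CPM. Gfi1b and Mef2c had counts in 5 libraries each, and Fli1 in 6. Stem cell marker genes had 3820 ± 944 and 5140 ± 1990 CPM, with 2 of 5 tested members higher. The 3 with a lower estimate were Slamf1 (803 ± 485 and 1380 ± 827 CPM), Esam (485 ± 238 and 892 ± 749 CPM) and Mllt3 (188 ± 128 and 268 ± 375 CPM). Without Tomato- replicate 1, which had 907 CPM, the Tomato- mean of Mllt3 was 108 CPM, below that of Tomato+, and 4 of 6 tested members of the list were higher. Of 22 listed genes of Flt3-expressing and granulocyte-monocyte progenitors, 5 had any count, with 32.7 ± 45.8 and 17.8 ± 26.9 CPM in sum. Without Tomato+ replicate 4 the Tomato+ sum was 17.1 CPM, and without Tomato- replicate 4 the Tomato- sum was 7.17 CPM.

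Glycolysis genes had 5450 ± 1360 and 5270 ± 971 CPM, with 4 of 7 tested members higher. Aldoa, an aldolase gene, had 1330 ± 535 and 697 ± 89.1 CPM (log2 fold change 1.15, SE 0.57), and the hexokinase gene Hk1 had 155 ± 135 and 905 ± 723 CPM. Nuclear-encoded subunits of the respiratory chain and ATP synthase had 4200 ± 623 and 5190 ± 843 CPM, with 16 of 25 tested members higher, translation factors 2900 ± 804 and 3220 ± 1390 CPM with 3 of 8 higher, and ribosomal proteins 783 ± 195 and 976 ± 299 CPM with 6 of 13 higher. Over the 10 tested lists, 0 passed with camera, with an estimated correlation (smallest adjusted p = 0.927) or with fry (smallest adjusted p = 0.797), and 0 had an unadjusted camera p under 0.05. For the lists of cytoskeleton, respiratory chain and glycolysis, camera's direction was down although the median log2 fold change was above 0, and for signalling, cytoskeleton and ribosomal proteins the median and the mean differed in sign. In up to 22 other settings, each of the 10 lists lost its majority of higher or lower members in at least 1, and the sign of its median turned in at least 1. Fry, which does not compare a list with other genes, gave the direction up for all 10 lists.

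**Figure D3:**
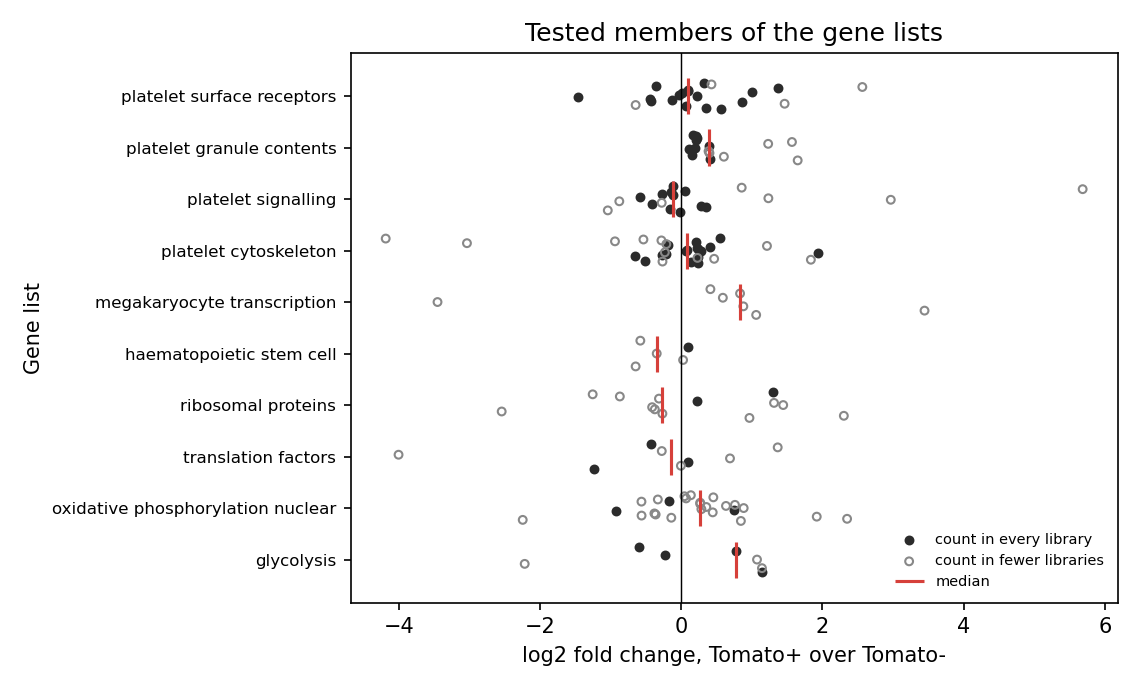
Log2 fold change of Tomato+ over Tomato- (horizontal axis) for each tested member of the 10 tested gene lists (vertical axis), with members counted in every library filled, others open, and the median as a red line. The 15 members of the granule list all lie above 0 and the other lists spread to both sides.

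Markers of other blood cells were mostly near 0 in both fractions. Lyz2, which encodes lysozyme of monocytes, macrophages and neutrophils, was an exception at 7670 ± 1120 CPM in Tomato+ and 7860 ± 1190 CPM in Tomato-, and F13a1, which platelets also express, had 1000 ± 475 and 711 ± 682 CPM. Neutrophil markers had 207 ± 239 and 147 ± 162 CPM in sum, with Clec4d at 132 ± 132 and 124 ± 130 CPM and S100a9 in 1 Tomato+ library alone. Without Tomato+ replicate 3 the Tomato+ sum of neutrophil markers was 113 CPM, below that of Tomato-, and without Tomato- replicate 4 the Tomato- sum was 94.7 CPM. Red cell markers had 1760 ± 328 and 1940 ± 1690 CPM, led by Beta-s and Bsg (743 ± 239 and 356 ± 333 CPM), and the Tomato- sum was 1200 CPM without replicate 4, below that of Tomato+. Of the B cell markers, Cd37 had counts in 2 Tomato+ libraries and Cd79a in none. Of the T and NK cell markers, Nkg7 had counts in 1 Tomato- library and Cd3e in none. Endothelial markers had 121 ± 117 CPM (77.4 without Tomato+ replicate 1) and 181 ± 86.5 CPM, with Tie1 at 48.7 ± 64.5 and 120 ± 71.6 CPM and Plvap at 72.1 ± 127 and 48.1 ± 65.8 CPM. Without Tomato+ replicate 3 the Tomato+ mean of Tie1 was 21.9 CPM, and without Tomato+ replicate 1 that of Plvap was 16.5 CPM.

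Libraries differed in the number of detected genes within each group. Tomato+ libraries had 1589 ± 531 detected genes and Tomato- libraries 1391 ± 712 (exact permutation p = 0.595, adjusted p = 0.595, n = 5 each). Replicates 1, 2 and 5 of Tomato- had 902, 978 and 807, and no Tomato+ library had fewer than 1118. Neither total counts (exact permutation p = 0.151, adjusted p = 0.337) nor the share of ribosomal protein counts (0.0783 ± 0.0195% and 0.0976 ± 0.0299%, exact permutation p = 0.270, adjusted p = 0.337) passed. The haemoglobin share, which is the row Beta-s alone since the other 4 haemoglobin rows had 0 counts, was 0.0130 ± 0.0132% and 0.0879 ± 0.135% (exact permutation p = 0.206, adjusted p = 0.337), with 0.326% in Tomato- replicate 4 (95% Wilson interval 0.322 to 0.329%). The 10 highest genes of a library took 38.6 ± 1.99% of counts in Tomato+ and 35.4 ± 0.884% in Tomato-, a difference of 3.20 percentage points that passed (exact permutation p = 0.00794, adjusted p = 0.0397, n = 5 each). That p is the smallest this design allows and needs complete separation, which rested on 0.0041 percentage points between Tomato+ replicate 1 (95% Wilson interval 36.58 to 36.64%) and Tomato- replicate 2 (36.57 to 36.64%), within counting error. The difference did not pass in 9 of 10 cases with 1 library left out (adjusted p = 0.0794 by exact permutation, 4 against 5 libraries), after thinning to the smallest total (exact permutation adjusted p = 0.0794) or paired by replicate number (exact p = 0.0625). The smallest adjusted p that the leave-out tests allow for 1 measure alone is 0.0794, and pairing allows none below 0.0625. Without Rn45s the difference was 2.21 percentage points and did not pass (exact permutation p = 0.103, adjusted p = 0.337).

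**Figure D4:**
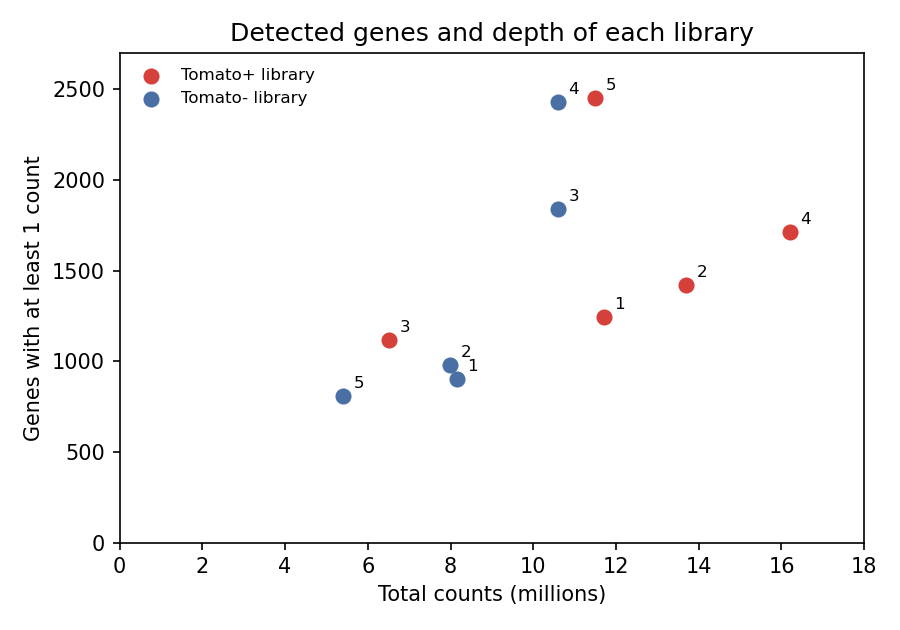
Detected genes (vertical axis) against total counts in M (horizontal axis) for each library, coloured by group and numbered by replicate. Tomato- replicates 1, 2 and 5 lie under 1000 detected genes, and Tomato+ replicate 5 and Tomato- replicate 4 have the most, 2450 and 2430.

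The data limit what an uncalled gene shows. Of 64 named genes with a count, 32 had a group mean that moved by over 1.5 times with 1 library left out, and in 14 the group with the higher mean changed. Of 255 tested genes with a count in every library, 44 (17.2%) had a 95% interval within 2-fold in the edgeR test of all genes. Of the 225 genes with 10 counts in every library, which carried 77.5% of counts, 71 (31.6%) had a 95% interval within 2-fold in edgeR run on those genes alone, a choice made after seeing the data, and 0 of them passed.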

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

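The values below come from 1 library each that lay far from the other 4 of its group, by a gap that exceeded the 95% critical value of Dixon's test, a rule set before the data were examined. Of 102 groups of values examined, 14 met this rule. Chance alone would give about 1 in 20 (5.1 of 102) for normally distributed values. Groups made mostly of 0 CPM are not so distributed, so the counts of groups that met the rule are not read as an excess. Several of these genes had counts in few libraries, so that a single library with counts stands apart by construction. No explanation was tested for these values.

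Tomato- replicate 4 had the highest haemoglobin share (0.326% of counts) and Beta-s level (3260 CPM) of its group, which are 1 measurement on different scales. Counted once, 13 of 100 groups met the rule, where chance would give about 5.0 for normally distributed values. In the same library Selp (24.5 CPM), Gata1 (62.4 CPM), Nkg7 (20.7 CPM) and Mgrn1 (4.44 CPM) lay above the other Tomato- libraries. Tomato+ replicate 3 stood apart for P2rx1 (2710 CPM), Mgrn1 (692 CPM) and S100a9 (240 CPM). Tomato+ replicate 5 stood apart for Selp (364 CPM) and Gata1 (46.7 CPM), and Tomato+ replicate 1 for the endothelial marker Plvap (294 CPM). Tug1 had 1100 CPM in Tomato- replicate 5, and Gp1ba had 1650 CPM in Tomato- replicate 2.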

How the results depend on the processing

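Settings chosen only after the results were seen were total-count scaling, the genes with 10 counts in every library, the sets without the 3 libraries under 1000 detected genes and, for the share of the 10 highest genes, the block, thinning and leaving out Rn45s, and an exact p from the absolute difference. The count of 0 genes called by edgeR stood in each of the other edgeR settings: other scaling factors, no filter or a stricter one, haemoglobin genes left out, thinning, a threshold of 0.10, the replicate block, and each library left out in turn (lowest 0, highest 0). It also stood in the settings chosen after seeing the data, which were total-count scaling, the 225 genes with 10 counts in every library with and without the block, and the smaller sets of libraries. The smallest adjusted p ranged from 0.0999 to 1 over these fits. With no filter 1764 of 4692 genes had an unadjusted p under 0.05, and the smallest adjusted p was 0.128. DESeq2 called 217 genes, 154 higher and 63 lower in Tomato+. Of these, 181 had no count in 1 group, and 2 (Tug1 and Mgrn1) were among the genes that edgeR tested. On the genes with 10 counts in every library, chosen after seeing the data, DESeq2 called 2, Tug1 (log2 fold change -6.02, adjusted p = 0.000990) and Clcn3 (-2.31, adjusted p = 0.0405), both lower in Tomato+. The count of lists called was 0 in the other edgeR settings above, with an estimated correlation and with fry; lists were not tested with DESeq2, with voom or at the threshold of 0.10. The share from mitochondrial genes and its alternatives were not run.

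The counts did not show a pairing of libraries by replicate number. The labels do not say whether same-numbered libraries share an animal, and weak correlations between such irregular libraries cannot exclude it. The deviations of same-numbered libraries correlated at 0.03, -0.03, -0.11, 0.12 and -0.033, and 2 of 5 Tomato+ libraries correlated best with their own number. With the replicate block edgeR called 0 genes (17 at an unadjusted p under 0.05), and the block on the genes with 10 counts in every library also gave 0. Limma voom with quality weights called 0 genes without the block and 2 with it, Rn45s (log2 fold change 0.18, SE 0.0035, adjusted p = 0.000576) and Nrgn (0.43, adjusted p = 0.00268). The cause was not tested. The exact sign-flip test of the 5 differences by number gave 3.20 percentage points for the share of the 10 highest genes, with p = 0.0625, the smallest 5 pairs allow, and it changed no other call of a share of counts.

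The difference in the share of the 10 highest genes was 2.40 to 3.71 percentage points with each library left out. With a p that doubles the smaller tail, 4 against 5 libraries give no p under 0.0159, and the difference passed in 1 of 10 cases (without Tomato+ replicate 3, adjusted p = 0.0397) and not in 9 (adjusted p = 0.0794). With an exact p from the absolute difference it passed in 4 of 10 (without Tomato+ replicate 1, 3, 4 or 5, adjusted p = 0.0397) and not in 6 (adjusted p = 0.0794). It was 2.21 without Rn45s, 3.21 after thinning (adjusted p = 0.0794) and 3.54 without the 3 libraries under 1000 detected genes, where 5 against 2 libraries cannot pass. The difference in log10 total counts was 0.0914 to 0.199, and it passed without Tomato+ replicate 3 (0.199, exact permutation adjusted p = 0.0397), but not with a p from the absolute difference (exact permutation adjusted p = 0.0595). The difference in detected genes was -17.2 to 458, and it turned negative without Tomato+ replicate 5. The cause was not tested for either.

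Over 33 named genes, 771 of 836 values in other settings kept their sign and their side of the threshold, 59 changed sign and 6 passed (Tug1 and Mgrn1 with DESeq2, Tug1 and Clcn3 with DESeq2 on the genes with 10 counts in every library, Rn45s and Nrgn with voom and the block). None of the genes that changed sign passed in any setting, and the cause was not tested. With the block, log2 fold changes that turned were 0.0086 for Itga2b and 0.93 for Gp1ba. With DESeq2 factors they were -0.0045 for Vwf, -0.064 for Itgb3 and -0.038 for Pf4, with no filter 0.036 for Itga2b, and with total counts -0.078 for Vwf, -0.12 for Itgb3, -0.11 for Pf4 and -0.034 for Lyz2. On the genes with 10 counts in every library they were -0.039 for Itgb3 and -0.031 for Pf4, and with the block there -0.054 for Itgb3 and -0.0072 for Pf4. Without the 3 libraries under 1000 detected genes they were -0.017 for Vwf, -0.10 for Itgb3, -0.11 for Gp9, -0.10 for Pf4, -0.44 for Tubb1 and -0.058 for Lyz2. Without Tomato+ replicate 3 as well they were -0.069 for Dap, -0.13 for Vwf, -0.043 for Itgb3, -0.21 for Gp9, -0.18 for Pf4, -0.32 for Tubb1, -0.062 for Cd9, -0.20 for Clu, -0.090 for Gng11, -0.15 for Zyx and -0.24 for Lyz2. With DESeq2 they were -0.051 for Itgb3 and -0.028 for Pf4, with DESeq2 on the genes with 10 counts in every library -0.027 for Vwf, -0.074 for Itgb3 and -0.057 for Pf4, with voom -0.0024 for Gp9, -0.0020 for Pf4, -0.055 for Clu, -0.12 for Slc2a3 and -0.089 for Lyz2, and with voom and the block 0.60 for Gp1ba, -0.065 for Gp9, -0.029 for Pf4, -0.065 for Clu, -0.022 for Gng11, -0.056 for Slc2a3 and -0.076 for Lyz2. With each library left out, genes that turned ranged over -0.94 to 0.62 for Gp1ba, -0.15 to 0.11 for Itga2b, -0.10 to 0.23 for Itgb3, -0.036 to 0.23 for Pf4 and -0.035 to 0.45 for Tubb1.

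Depth limited detection little: with 50% of its reads drawn, a library kept 89.9 to 97.1% of its detected genes. Of the 4692 genes with a count, 2008 had it in 1 library alone, at a median of 114 counts.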

Other observations

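Of the tests below, those of depth, of total counts and of other blood cells for detected genes, of other markers for Lyz2, of Rn45s, of detected genes and of thinning for the 10 highest genes, and all counts of splits were chosen after the results they measure had been seen.

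Lists too sparse to test had the following levels, given as CPM in Tomato+ and then Tomato- (mean ± SD, n = 5 each). MHC class I and antigen processing genes had 11100 ± 1720 and 12200 ± 997 CPM, of which B2m, the invariant light chain, took most (0.984 ± 0.155% and 1.08 ± 0.184% of counts; B2m was chosen after its values were seen). MHC class II genes had 0 and 15 ± 33.5 CPM, from 1 of 11 genes in Tomato- replicate 4 alone. Genes that set platelet lifespan (BCL-2 family and caspases) had 2400 ± 404 and 1930 ± 679 CPM. Interferon-stimulated genes had 1040 ± 526 and 984 ± 809 CPM (629 without Tomato- replicate 5). Immediate-early and heat-shock genes had 483 ± 818 CPM (118 without Tomato+ replicate 3) and 576 ± 611 CPM (382 without Tomato- replicate 5), and proteasome subunits 312 ± 234 and 505 ± 409 CPM. Proliferation genes had 57.8 ± 71.6 CPM (27.0 without Tomato+ replicate 3) and 8.27 ± 18.5 CPM (0 without Tomato- replicate 4), from 4 of 27 genes. The sums over B cell markers were 30.6 ± 49.9 CPM (9.54 without Tomato+ replicate 4) and 0 CPM, over T and NK cell markers 0 and 4.13 ± 9.24 CPM (Tomato- replicate 4 alone), and over monocyte and macrophage markers 8670 ± 1390 and 8580 ± 1530 CPM.

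Inflammatory and innate immune genes had 645 ± 1230 and 282 ± 70.6 CPM, with most of the Tomato+ sum in replicate 3 (96.1 CPM without it, below the Tomato- sum). That library alone had Il1b (1520 CPM), Casp1 (796 CPM) and the immediate-early gene Atf3 (906 CPM), which were at 0 in the other 9 libraries and were chosen after their values were seen.

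Detected genes ranged from 807 to 2450 per library, and a multidimensional scaling of all libraries set apart the 4 with the fewest on its leading dimension (30.9% of variance), 3 of them Tomato- and 1 Tomato+. Sequencing depth as the whole cause is argued against by thinning, after which the largest number was still 2.95 times the smallest. A candidate explanation is that fewer RNA molecules were captured in some libraries: the spread of the 225 genes with 10 counts in every library around their mean profile fell as detected genes rose (Spearman rho = -0.9, permutation p = 0.0009, adjusted p = 0.0036 over 4 relations, n = 10; Pearson r = -0.85, permutation p = 0.00258, adjusted p = 0.0103, and -0.79 without the 2 libraries farthest from the median). RNA of other blood cells stays open, since detected genes and the sum of 102 markers of other cells gave rho = 0.67 (permutation p = 0.0382, adjusted p = 0.0764) and r = 0.65 (permutation p = 0.0120, adjusted p = 0.0240), but r = 0.44 without the 2 farthest libraries, and with the 6 markers found in platelet libraries kept in, which were left out after their values were seen, rho = 0.55 (permutation p = 0.104, adjusted p = 0.104), r = 0.61 (permutation p = 0.0611, adjusted p = 0.0815) and r = 0.15 without the 2 farthest. For total counts rho was 0.62 (permutation p = 0.0591, adjusted p = 0.0788) and r was 0.53 (permutation p = 0.116, adjusted p = 0.116, and 0.77 without the 2 farthest).

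Lyz2 took 0.776% of counts on average and had 5880 to 9030 CPM in every library. RNA from monocytes, macrophages or neutrophils, cells that a sort of platelets should remove, would bring the other abundant transcripts of these cells. The other 37 listed markers, without F13a1, which platelets express, summed to at most 0.0672 of the Lyz2 level in any library, and 9 of them had a count, which argues against such cells as the main source. Reads of the paralog Lyz1 are argued against as well, since its counts were at most 0.000238 of those of Lyz2. Transcription of Lyz2 in megakaryocytes or its uptake by platelets may remain as explanations and was not tested.

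The 10 highest genes took a larger share of counts in Tomato+ than in Tomato- libraries, a call that rested on 0.0041 percentage points between 2 libraries. Deeper sequencing of Tomato+, as random sampling of more reads, is argued against, because such sampling keeps shares of counts by construction. The difference was 3.20 percentage points with all reads and 3.21 after thinning (exact permutation p = 0.0159, adjusted p = 0.0794). Thinning was therefore no separate test, and other effects that go with depth were not tested. Rn45s is among these genes, at 5.52 ± 1.64% of counts in Tomato+ and 3.80 ± 1.38% in Tomato-, so its larger mean is part of the difference by construction. Tmsb4x (12.8 ± 1.46% and 11.4 ± 1.35%) is part of it in the same way. Tsc22d1, named for its rank after its values were seen, went the other way (2.46 ± 0.332% and 2.76 ± 0.691%). Without Rn45s the difference was 2.21 percentage points (exact permutation p = 0.103), which neither excludes nor establishes Rn45s as the whole cause. Fewer detected genes in Tomato+ cannot be told apart from chance spread, as Tomato+ libraries had on average 198 more with an exact permutation p of 0.595. A difference between the platelet fractions themselves stays open and was not tested apart from these.

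Other splits of the 10 libraries into 5 and 5 were compared with the real split. For genes called by edgeR and for gene lists the real count was 0, so 100 of 100 splits were as large by construction and nothing follows about chance; the highest other split gave 1 in each case. At an unadjusted p under 0.05 in edgeR the real split gave 9 genes, 31 of 100 splits gave as many, and the highest other gave 41. Genes detected in 4 or 5 libraries of a group and in none of the other numbered 10 in the real split, 72 of 126 splits gave as many, and the highest other gave 113. Chance is not excluded for these last counts, and splits with several times the real count point to a structure of the libraries apart from the groups. Proser2 was the 1 gene with counts in all 5 libraries of a group (Tomato+) and none of the other, and it was chosen after its values were seen.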
